A study of Homo sapiens with 9 samples.

How the data were processed

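For each of 3 MDA-MB-231 lines (sensitive cells and lines resistant to docetaxel or to paclitaxel), total RNA was taken from 3 separate passages. From 5 µg each, biotin-labelled RNA was hybridized to Affymetrix human genome expression arrays, 9 in all. The deposited values are a probe set intensity on a linear scale, 1 value per probe set and array; the submitters' processing notes name Affymetrix Expression Console 1.1.2 and PLIER, a method that summarizes probes into probe sets. Background correction, between-array normalization by the authors and detection calls are not given in the sources used here. All 9 columns of values were used. No reads or counts exist for arrays, so the number of arrays and the signal over background set the precision.

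The table held 22283 probe sets, of which 68 were control probe sets and 22215 human ones. Of the human ones 19065 named 1 gene, 1043 several and 2107 none, and 19053 of the first had a gene identifier in the RefSeq gene table, from which symbols, chromosome and gene order were taken (no coordinates are printed). Per gene the probe set with the highest mean over all arrays was kept, which gave 11963 genes, 4310 of them with more than 1 probe set. Values became log2(intensity + 16). The array medians then differed by 0.27, more than the 0.2 set as the limit, so the arrays were quantile-normalized. With this offset a difference that starts from a low intensity is understated, and values near 0 hold no order. At the level of probe sets 3922, 4128 and 356 of 22215 were called in the docetaxel, paclitaxel and between-line comparisons.

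All tests were run in R 4.3.3 with limma 3.58.1: 1 linear model with 3 group means, moderated by eBayes (6 residual and 5.40 prior degrees of freedom), with 3 contrasts (docetaxel-resistant minus sensitive, paclitaxel-resistant minus sensitive, paclitaxel- minus docetaxel-resistant) and a moderated F test. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes within a contrast, and called below 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 22 lists within a contrast, and again with an estimated correlation. The lists held 731 genes, 664 of them measured: drug efflux and uptake transporters, tubulins, microtubule-associated and microtubule-regulating proteins, mitosis and spindle checkpoint, DNA replication and G1/S, apoptosis regulators, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory cytokines, epithelial genes, mesenchymal genes, matrix proteases and their inhibitors, integrins and cell adhesion, glycolysis and hypoxia, cholesterol and lipid synthesis, unfolded protein and integrated stress response, heat shock proteins, xenobiotic metabolism and glutathione, receptor tyrosine kinases and growth factors, stem-cell and Notch or Wnt genes, oxidative phosphorylation, and ribosomal proteins. Markers of luminal breast, fibroblast, melanocytic and blood cells were described by counts and medians. The groups, tests, lists, markers, alternative settings and the rule for named genes were fixed before the data were examined.

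Genes were named by this rule: per contrast, the 10 largest increases and 10 largest decreases among called genes whose 3 arrays of 1 group all lay above the 3 of the other and whose higher group mean was above the median of all genes; up to 4 members with the smallest adjusted p of each called list; ABCB1, ABCC1, ABCG2, TUBB3, TUBB2A, TUBB6, MAPT, STMN1, BCL2, BCL2L1, MCL1 and CDKN1A always; and up to 5 genes called in both lines in opposite directions with the largest difference. Other members of lists, marker genes and chromosomal neighbours were named after their values were seen.

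The procedure was tested on simulated data with 9 arrays and 11963 genes, of which 67, 67 and 66 changed. Of changes of 0.5, 1 and 2 on the log2 scale it recovered 7.46%, 94.0% and 100% in the docetaxel comparison, 5.97%, 91.0% and 100% in the paclitaxel comparison and 11.9%, 91.0% and 100% between the lines. Of the genes called there, 8 of 142, 8 of 139 and 4 of 139 were unchanged ones. The simulated noise was independent between genes and between arrays. In the real arrays 1 axis held 43.4% of the variance within groups, so these shares may not carry over to the real data. The overlap of the 2 comparisons with sensitive cells was set against 100 simulated data sets with unchanged groups and shared controls.

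Array quality was checked on the control probe sets. The 3' minus 5' log2 difference of GAPDH ran from 0.0067 to 0.20, and that of beta-actin was 0.17 in paclitaxel-resistant replicate 1 and at most -0.02 elsewhere. For GAPDH the paclitaxel-resistant arrays (0.094 to 0.20) all lay above the sensitive ones (0.014 to 0.039). The docetaxel-resistant arrays ran from 0.0067 to 0.13. The spiked bioC control read 221 in sensitive replicate 3 and 41.5 to 72.0 elsewhere. At most 0.234% of probe sets held identical values in a pair of arrays. The median deposited intensity was 36.2, 33.7 and 39.1 in sensitive, 39.2, 41.2 and 43.9 in docetaxel-resistant and 41.8, 37.5 and 38.7 in paclitaxel-resistant replicates 1 to 3. No scan date or batch is given in the sources used here.

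Alternatives were values as deposited, median centring, a pseudocount of 1, a filter at the median level, the mean of a gene's probe sets, probe sets without names ending in _x_at or _s_at, a mean-variance trend with robust spread, array weights, the replicate number as a block, each array left out in turn, only the 2 groups compared, stricter thresholds and an estimated correlation. After the data were seen, a fit without the arrays of lowest and highest median and a fit with the first principal component of the within-group deviations as a covariate were added.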

Results

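The data are Affymetrix human genome microarray profiles of total RNA from MDA-MB-231, an established human breast cancer cell line of the mammary gland that grows as an adherent culture. The 9 arrays form 3 groups of 3, each array from a separate passage. Each resistance is represented by 1 line, so standard errors and p-values reflect the spread among passages, not among separately selected lines. Sensitive cells were kept in medium with 1 µM verapamil, a calcium channel blocker that also inhibits P-glycoprotein, a drug efflux pump. The docetaxel-resistant line was kept with verapamil and 2 nM docetaxel, and the paclitaxel-resistant line with verapamil and 7 nM paclitaxel. The sensitive cells had no docetaxel or paclitaxel, so drug in the medium and selected line change together in both comparisons with them. Both drugs are taxanes, which bind and stabilize microtubules. They differ in that docetaxel carries a tert-butoxycarbonyl group where paclitaxel has a benzoyl group on the side chain, and a free hydroxyl where paclitaxel has an acetyl ester at carbon 10. The median deposited intensity per array ran from 33.7 to 43.9, and between 24.0% and 27.0% of the probe sets lay under an intensity of 16. Across genes, which are not independent replicates, arrays of 1 group correlated at r = 0.967 to 0.992, docetaxel- with paclitaxel-resistant arrays at 0.964 to 0.980, and resistant with sensitive arrays at 0.889 to 0.954. With 3 arrays per group the median standard error of a log2 difference was 0.16, and the number of arrays limits the precision.

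The first comparison asks how the docetaxel-resistant line differed from sensitive cells. ABCB1, which encodes P-glycoprotein, rose by 5.41 ± 0.19 on the log2 scale (SE, n = 3 per group, adjusted p = 1.01e-08), from a mean deposited intensity of 7.35 ± 2.65 (SD) to 1025 ± 292. CD74, the invariant chain that accompanies class II antigen-presenting molecules, fell by 7.33 ± 0.22 (adjusted p = 2.87e-09), from 11082 ± 935 to 52.8 ± 9.58. MGMT, the enzyme that removes alkyl groups from guanine in DNA, fell by 6.60 ± 0.14 (adjusted p = 3.15e-10), and FSCN1, the actin-bundling protein fascin, fell by 4.65 ± 0.16 (adjusted p = 9.63e-09). LCP1, the actin-bundling protein plastin of blood cells, rose by 4.18 ± 0.21 (adjusted p = 1.46e-07). The largest increases also took in the cancer-testis antigens MAGEC1 (4.03 ± 0.13) and MAGEA1 (3.08 ± 0.18) and the monocyte-attracting chemokine CCL2 (3.66 ± 0.27). Further ones were the deubiquitinase USP33 (3.97 ± 0.31), WDR3 (3.96 ± 0.28), the adhesion receptor ADGRE1 (3.76 ± 0.18), IGSF3 and TMEM243 (3.11 ± 0.24). Without probe sets whose names end in _x_at or _s_at the value of USP33 was 0.98, and with a pseudocount of 1 those of MAGEC1 and MAGEA1, low in sensitive cells, were 6.97 and 6.52. The largest decreases also took in ADIRF (-6.50 ± 0.16), the cancer-testis antigen SPANXB1 (-6.07 ± 0.17) and the class II chains HLA-DRB1 (-5.25 ± 0.21) and HLA-DRA (-4.95 ± 0.17). Further ones were the cell cycle regulator RGCC (-5.09 ± 0.15), the anion transporter SLCO4A1 (-4.93 ± 0.25) and ZSCAN18 (-4.53 ± 0.28), and HLA-DRA stood at -8.22 with a pseudocount of 1. The adjusted p of these genes lay between 3.15e-10 and 7.62e-06, and in each the 3 arrays of 1 group all lay above the 3 of the other.

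The rise of ABCB1 was part of a run of raised neighbours on chromosome 7. Of the 5 measured genes before it in chromosomal order, DMTF1 rose by 1.42 ± 0.34, TMEM243 by 3.11 ± 0.24, TP53TG1 by 1.92 ± 0.16 and CROT, a peroxisomal carnitine transferase, by 2.92 ± 0.18. ABCB4, the phospholipid transporter next to ABCB1, rose by 1.95 ± 0.23. The call of DMTF1 ended without the arrays of lowest and highest median and with the first axis of within-group variation as a covariate. The measured genes on either side did not pass the test, with 0.04 in GRM3, 0.42 in RUNDC3B and -0.03 in SLC25A40. In the paclitaxel-resistant line ABCB1 rose by 1.72 ± 0.19 (adjusted p = 0.000116), CROT rose by 0.99 ± 0.18 (adjusted p = 0.00235) and TP53TG1 by 0.59 ± 0.16 (adjusted p = 0.0234). The call of TP53TG1 there ended without sensitive replicate 2 and without paclitaxel-resistant replicate 1 or 3, at an adjusted p of up to 0.0853, and without the arrays of lowest and highest median. TMEM243 stood at 0.66 (adjusted p = 0.0763), DMTF1 at 0.49 (adjusted p = 0.364) and ABCB4 at -0.11 (adjusted p = 0.800), none of them called.

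**Figure D1:**
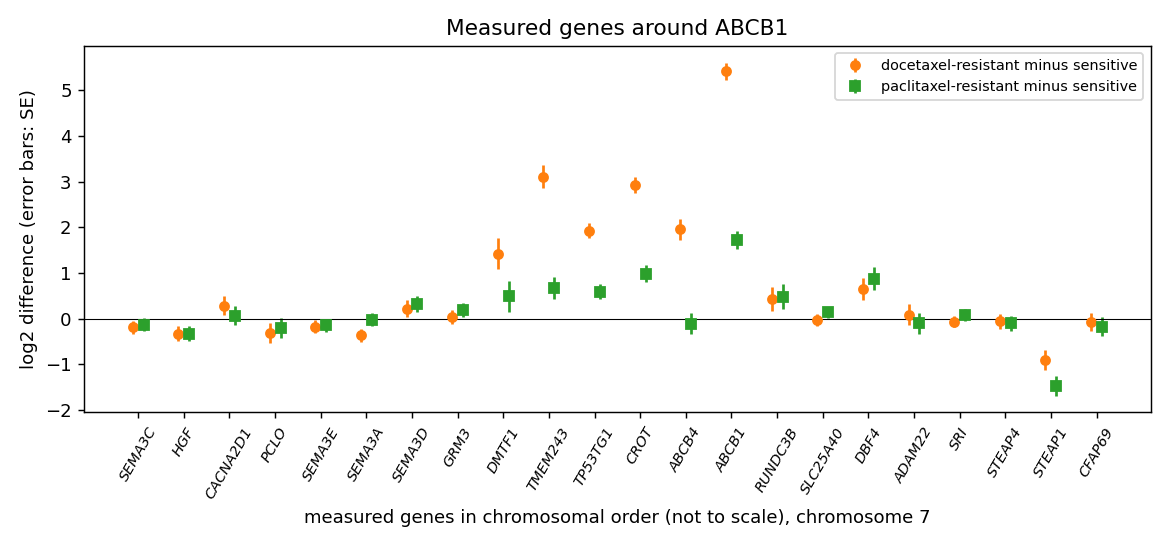
Log2 difference of each resistant line from sensitive cells (vertical axis; bars, SE) for the measured genes around ABCB1 on chromosome 7, in chromosomal order and not to scale. In the docetaxel-resistant line the genes from DMTF1 to ABCB1 lie between 1.42 and 5.41, while in the paclitaxel-resistant line ABCB1 lies at 1.72 and ABCB4 at -0.11.

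Of the 22 gene lists fixed before the data were examined, 5 were called in this comparison. Antigen presentation was lower: 13 of 22 measured members fell, none rose and 9 were not called, with 13 lower when adjusted over the list alone (median log2 difference -0.57, adjusted p = 2.50e-06 for the list, adjusted p = 0.290 with an estimated correlation). Its fallen members included HLA-DPA1 (-2.11 ± 0.25) and HLA-DMA, which loads peptides onto class II molecules (-1.79 ± 0.22). The 9 measured markers of blood cells had a median difference of 0.01, with LCP1 at 4.18. SRGN, HBB and CD53 had mean intensities of 1269, 378 and 106 in sensitive cells, and the others lay near background. A further probe set of HLA-DPA1 stood at -0.22 in the docetaxel- and -0.08 in the paclitaxel-resistant line, and the mean of its probe sets at -1.28 in the former. Cholesterol and lipid synthesis was higher: 12 of 24 rose, 2 fell and 10 were not called, with 14 higher and 2 lower adjusted over the list alone (adjusted p = 2.54e-05, and adjusted p = 0.290 with an estimated correlation). Among them were HMGCS1, which makes the mevalonate precursor (2.46 ± 0.30), ACAT2 (1.42 ± 0.20), the fatty acid synthesis enzyme ACACA (1.19 ± 0.14) and the sterol synthesis enzyme HSD17B7 (1.06 ± 0.12). The lower-level probe set of ACACA went the other way, and the mean of its probe sets was 0.39. In the list of NF-kB and inflammatory cytokines 14 of 32 fell, 3 rose and 15 were not called, with 16 lower and 3 higher adjusted over the list alone (adjusted p = 0.00171, and adjusted p = 0.479 with an estimated correlation). The inflammatory cytokine IL6 fell by 3.79 ± 0.29 and the leukocyte adhesion molecule ICAM1 fell by 2.43 ± 0.19. The interleukin receptor IL7R rose by 2.76 ± 0.17 and CCL2 by 3.66, and IL7R stood at 6.27 with a pseudocount of 1. In the list of glycolysis and hypoxia 13 of 34 fell, 3 rose and 18 were not called, with 16 lower and 3 higher adjusted over the list alone (adjusted p = 0.00278, and adjusted p = 0.290 with an estimated correlation). NDRG1 fell by 1.99 ± 0.15, the glycolytic regulator PFKFB3 by 1.39 ± 0.14 and BNIP3 by 1.19 ± 0.18, and the glycolytic enzyme ALDOC rose by 1.22 ± 0.21. In the list of matrix proteases and their inhibitors 9 of 35 fell, 2 rose and 24 were not called, with the same numbers adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.290 with an estimated correlation). The inhibitor TIMP3 fell by 3.82 ± 0.15, the protease ADAM8 by 2.57 ± 0.18, the plasminogen activator PLAT by 2.14 ± 0.23 and the lysosomal protease CTSD by 1.18 ± 0.17. None of the 5 stayed called with an estimated correlation, and another split of the 6 arrays called 6 lists at the preset one. Without probe sets whose names end in _x_at or _s_at the lists of matrix proteases (adjusted p = 0.191) and of glycolysis and hypoxia (adjusted p = 0.0671) were no longer called. Without sensitive replicate 2, and without docetaxel-resistant replicate 3, 8 lists were called, the added ones being the unfolded protein response, heat shock proteins and xenobiotic metabolism. The unfolded protein response was also called higher without sensitive replicate 3 (adjusted p = 0.0104). Heat shock proteins were also called higher without docetaxel-resistant replicate 2 (adjusted p = 0.0453) and with a mean-variance trend and robust spread (adjusted p = 0.0488).

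Of 17 measured drug transporters ABCB1 and ABCB4 rose, ABCC10 fell by 0.51 and 14 were not called (adjusted p = 0.490 for the list). The call of ABCC10 ended with some single arrays left out, with an adjusted p of up to 0.112. ABCC1 (-0.22, 95% interval -0.55 to 0.10) and ABCG2 (-0.16, interval -0.52 to 0.19), both efflux pumps, did not pass the test. Of 16 tubulins TUBA4A fell by 1.24 ± 0.15 and TUBA1C by 0.36 ± 0.11, and the call of TUBA1C ended with any 1 of the 9 arrays left out, at an adjusted p of up to 0.118 (adjusted p = 0.169 for the list). The beta-tubulin TUBB3 stood at -0.20 (interval -0.48 to 0.08), TUBB2A at -0.13 (-0.42 to 0.17), TUBB6 at -0.28 (adjusted p = 0.149) and the microtubule-destabilizing STMN1 at -0.22 (-0.50 to 0.06), none of them called. Of 35 microtubule-associated proteins 6 rose and 3 fell (adjusted p = 0.101). Of 30 apoptosis regulators 2 rose and 9 fell, among them the death receptor adaptor FADD at -0.85 ± 0.14 (adjusted p = 0.189 for the list). CDKN1A, the cell cycle inhibitor p21, fell by 0.78 ± 0.18 (adjusted p = 0.00917). The call of CDKN1A ended without the arrays of lowest and highest median (adjusted p = 0.0847) and with the within-group axis as a covariate (adjusted p = 0.0649). BCL2 (-0.24) and MCL1 (0.56 ± 0.20, adjusted p = 0.0673) were not called, and only the filter on genes at or above the median level brought MCL1 past the threshold, whereas without probe sets ending in _x_at or _s_at its difference was -0.21.

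The remaining 13 lists were not called. Mitosis and spindle checkpoint had 6 members higher and 6 lower of 35 (adjusted p = 0.975), DNA replication 4 and 6 of 34 (0.834) and interferon-stimulated genes 8 and 6 of 43 (0.317). Epithelial genes had 6 and 4 of 27 (0.372), mesenchymal genes 6 and 8 of 35 (0.352) and integrins and cell adhesion 4 and 8 of 36 (0.520). The unfolded protein response had 6 and 2 of 29 (0.0596), heat shock proteins 7 and 0 of 19 (0.0596) and xenobiotic metabolism and glutathione 2 and 12 of 37 (0.101). Receptor tyrosine kinases and growth factors had 9 and 9 of 41 (0.903), stem-cell genes 6 and 5 of 28 (0.886), oxidative phosphorylation 6 and 1 of 39 (0.240) and ribosomal proteins 0 and 0 of 26 (0.851). Oxidative phosphorylation was called higher without sensitive replicate 1 (adjusted p = 0.0418), and mitosis lower with the covariate (0.0493). Adjusted over the list alone, the unfolded protein response had 9 higher and 2 lower and the interferon-stimulated genes 10 and 7. Among their members, named after their values were seen, the interferon-induced BST2 fell by 4.51 ± 0.20 and IFI27 fell by 3.41 ± 0.22, while GBP1 rose by 1.54 ± 0.28. The matrix protein SPARC rose by 2.99 ± 0.14, the metastasis-associated S100A4 fell by 3.14 ± 0.15, and the ketosteroid reductase AKR1C3 fell by 1.58 ± 0.26. The median and the mean of the interferon list differed in sign, as did those of the mitosis, receptor kinase and ribosomal lists. Among markers of other cell types, 4 of 12 luminal breast genes rose (FOXA1, TFF3, AGR2 and SPDEF; median 0.17), with TFF3 at 2.37 ± 0.27. AGR2 lost its call without sensitive replicate 2 and without docetaxel-resistant replicate 3, at an adjusted p of up to 0.0608, and SPDEF with the mean of its probe sets. The melanocytic regulator MITF rose by 2.03 ± 0.20, while the 7 measured melanocytic markers had a median of -0.17. Of 11 fibroblast markers PDGFRB and FBN1 rose and COL6A3 fell (median -0.10), the call of PDGFRB ending without the arrays of lowest and highest median.

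In total 2510 of 11963 genes were called in the docetaxel comparison with limma at an adjusted p below 0.05, 1288 higher and 1222 lower, against 3895 at an unadjusted p below 0.05. Of the called genes 774 changed at least 2-fold (514 higher, 260 lower), and 10 rose and 27 fell at least 8-fold. In 4407 genes (36.8%) the arrays of the groups did not overlap, where chance gives 10%. The count was 1643 without docetaxel-resistant replicate 3 and 1338 without the arrays of lowest and highest median.

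**Figure D2:**
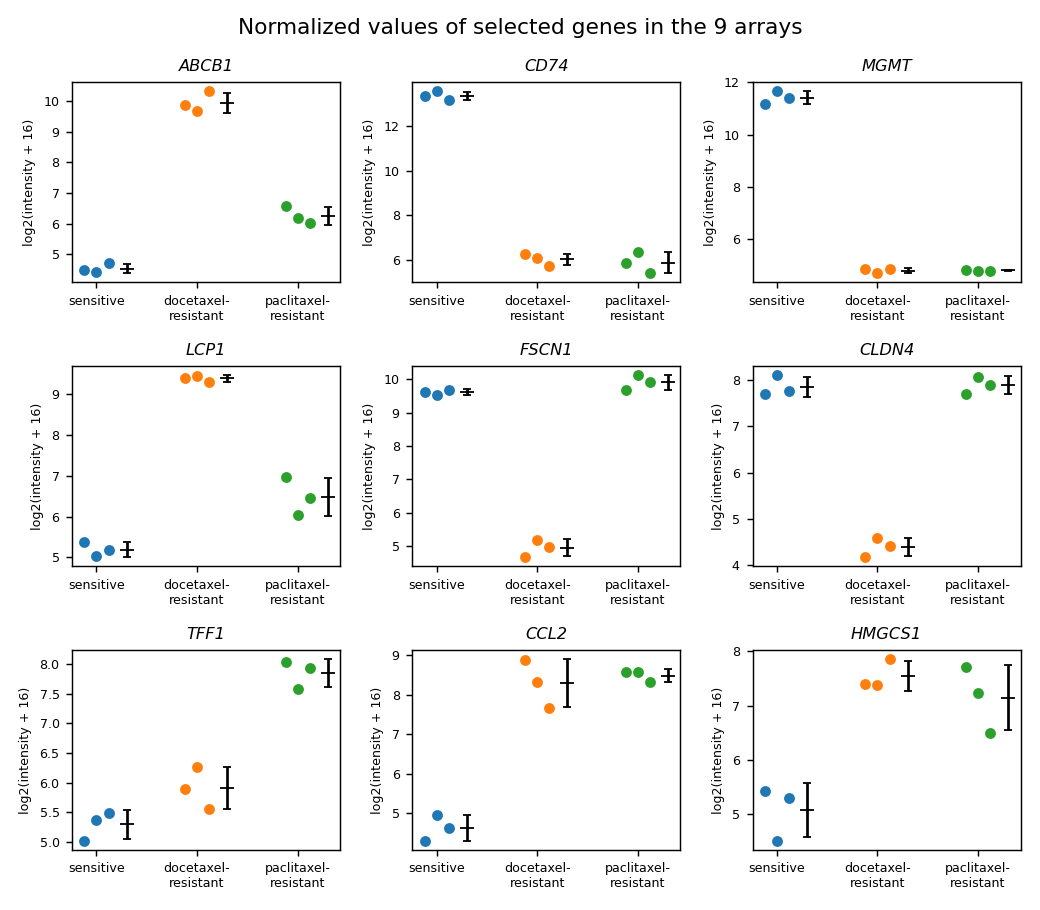
Log2(intensity + 16) after quantile normalization (vertical axis) in each of the 9 arrays, by group, for 9 genes, with the group mean and its SD. ABCB1, LCP1 and CCL2 rose in both resistant lines and CD74 and MGMT fell in both, whereas FSCN1 and CLDN4 were low in the docetaxel-resistant arrays alone.

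The second comparison asks the same of the paclitaxel-resistant line. CD74 fell by 7.48 ± 0.22 (SE, n = 3 per group, adjusted p = 2.39e-09), MGMT by 6.59 ± 0.14 (adjusted p = 3.17e-10) and ADIRF fell by 6.41 ± 0.16 (adjusted p = 7.45e-10). ADGRE1 rose by 4.22 ± 0.18 (adjusted p = 8.50e-08), the secreted trefoil peptide TFF3 by 4.02 ± 0.27 (adjusted p = 3.75e-06), CCL2 by 3.85 ± 0.27 and IL7R by 3.43 ± 0.17. ABCB1 rose by 1.72 ± 0.19 (adjusted p = 0.000116), to a mean deposited intensity of 63.0 ± 21.3 (SD). The largest increases also took in MAGEC1 (2.92 ± 0.13), IGSF3 (2.89 ± 0.14), the adhesion receptors ADGRF5 (2.81 ± 0.23) and ADGRG6 (2.57 ± 0.28), the DNA polymerase POLM (2.77 ± 0.28) and the spindle positioning protein MISP (2.62 ± 0.16). The largest decreases also took in SPANXB1 (-6.12 ± 0.17), HLA-DRB1 (-5.15 ± 0.21) and HLA-DRA (-4.94 ± 0.17). Further ones were RGCC (-4.91 ± 0.15), the microfibril protein MFAP2 (-4.22 ± 0.19), SLCO4A1 (-4.17 ± 0.25) and the nicotinamide methyltransferase NNMT (-4.17 ± 0.21). With a pseudocount of 1 ABCB1 stood at 2.91, IL7R at 7.02, MAGEC1 at 5.76, ADGRG6 at 3.88, HLA-DRA at -8.04 and MFAP2 at -6.51. In each of these genes the 3 arrays of 1 group all lay above the 3 of the other.

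Of the 22 lists, 6 were called. Antigen presentation was lower, with 12 of 22 members fallen, none risen and 10 not called, and 14 lower adjusted over the list alone (adjusted p = 1.74e-07, and adjusted p = 0.352 with an estimated correlation). HLA-DMA fell by 2.26 ± 0.22, and the 9 blood cell markers had a median of -0.04. Cholesterol and lipid synthesis was higher, with 13 of 24 risen, none fallen and 11 not called, and 15 higher and 1 lower adjusted over the list alone (adjusted p = 7.52e-06, and adjusted p = 0.352 with an estimated correlation). ACACA rose by 1.60 ± 0.14, FASN, the fatty acid synthase, by 1.71 ± 0.23, ACAT2 by 1.45 ± 0.20 and HSD17B7 by 1.19 ± 0.12. The lower-level probe sets of ACACA and FASN did not rise, and the means of their probe sets were 0.45 and 0.84. In the list of NF-kB and inflammatory cytokines 12 of 32 fell, 3 rose and 17 were not called, with 15 lower and 3 higher adjusted over the list alone (adjusted p = 0.00327, and adjusted p = 0.539 with an estimated correlation). IL6 fell by 3.77 ± 0.29 and the chemokine CXCL1 fell by 3.33 ± 0.29. Of the matrix proteases and their inhibitors 11 of 35 fell, 1 rose and 23 were not called, with 13 lower and 1 higher adjusted over the list alone (adjusted p = 0.00327, and adjusted p = 0.352 with an estimated correlation). TIMP3 fell by 2.67 ± 0.15, PLAT fell by 1.84 ± 0.23, the urokinase gene PLAU by 1.56 ± 0.15 and the protease inhibitor SERPINE2 by 1.21 ± 0.14. Of the microtubule-associated and microtubule-regulating proteins 10 of 35 rose, 2 fell and 23 were not called, with 11 higher and 2 lower adjusted over the list alone (adjusted p = 0.0326, and adjusted p = 0.352 with an estimated correlation). The microtubule-binding MID1 rose by 1.35 ± 0.18, the microtubule polymerase CKAP5 by 1.26 ± 0.19 and CLIP2 by 0.82 ± 0.16, and the tubulin folding cofactor TBCC fell by 1.32 ± 0.15. Of the unfolded protein response 8 of 29 rose, 3 fell and 18 were not called, with 12 higher and 4 lower adjusted over the list alone (adjusted p = 0.0451, and adjusted p = 0.563 with an estimated correlation). The endoplasmic reticulum chaperones HSP90B1 and CANX rose by 1.68 ± 0.22 and 1.37 ± 0.19, CRELD2 by 0.86 ± 0.14 and EDEM1 by 0.73 ± 0.13. With the mean of the probe sets MID1 stood at 0.81 and HSP90B1 at 0.88. None of the 6 stayed called with an estimated correlation.

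Without probe sets ending in _x_at or _s_at, the lists of matrix proteases (adjusted p = 0.216), of NF-kB (0.0602), of microtubule-associated proteins (0.212) and of the unfolded protein response (0.353) were no longer called. The list of microtubule-associated proteins also lost its call with genes at or above the median level only (adjusted p = 0.145). The unfolded protein response also lost its call without sensitive replicate 1 (adjusted p = 0.357), without docetaxel-resistant replicate 3 (0.0505) and without paclitaxel-resistant replicate 1 (0.106), and in 12 of 20 settings altogether, whose adjusted p ran from 0.00768 to 0.357.

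**Figure D3:**
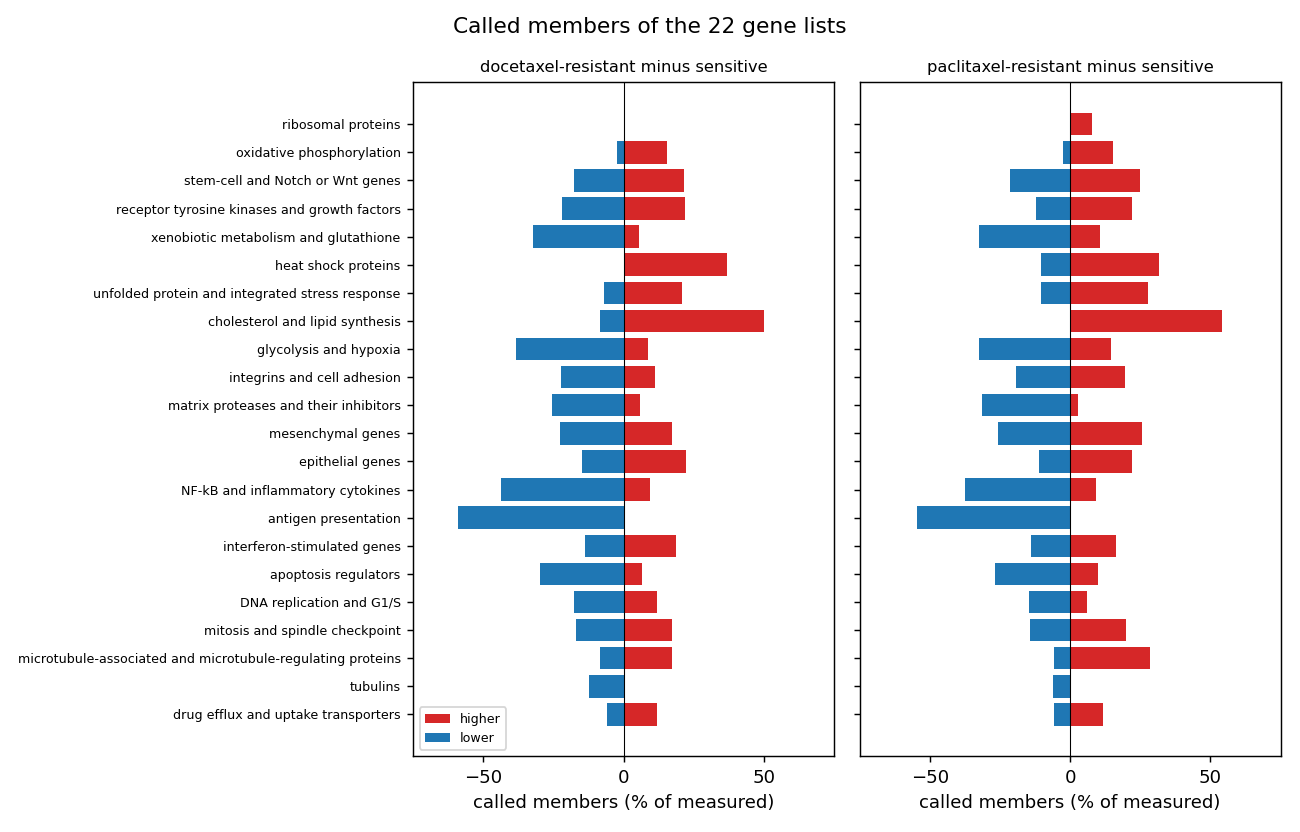
Called members of each of the 22 gene lists in each resistant line against sensitive cells, as the share of measured members that were higher (to the right) or lower (to the left), in percent. In both lines 12 or more members of antigen presentation fell with none risen, and 12 or more members of cholesterol and lipid synthesis rose.

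Among genes named in advance, the microtubule-binding protein tau, MAPT, rose by 0.53 ± 0.14 in the paclitaxel-resistant line (adjusted p = 0.0185). This call ended without sensitive replicate 2 (adjusted p = 0.0528), without paclitaxel-resistant replicate 2 (0.0642), without paclitaxel-resistant replicate 3 (0.0553) and without the arrays of lowest and highest median (0.0609). The apoptosis inhibitor BCL2L1 fell by 0.43 ± 0.13 in the docetaxel-resistant line (adjusted p = 0.0374) and by 0.45 ± 0.13 in the paclitaxel-resistant line (adjusted p = 0.0316). The docetaxel call of BCL2L1 ended without sensitive replicate 1 (adjusted p = 0.0737), 2 (0.0825) or 3 (0.0763), without docetaxel-resistant replicate 2 (0.0769) or 3 (0.152) and without paclitaxel-resistant replicate 2 (0.0535). The paclitaxel call of BCL2L1 ended without sensitive replicate 1 (adjusted p = 0.0677), 2 (0.0686) or 3 (0.0678), without docetaxel-resistant replicate 2 (0.0508) and without paclitaxel-resistant replicate 2 (0.0761) or 3 (0.104). Over all 20 settings these calls ended in 11 and 10, and with the mean of its probe sets the paclitaxel value of BCL2L1 was -0.81. In the paclitaxel-resistant line ABCC1 (-0.24), ABCG2 (-0.06), TUBB3 (0.16), TUBB2A (-0.12), TUBB6 (-0.28), STMN1 (-0.23), BCL2 (-0.19), MCL1 (0.47) and CDKN1A (-0.31) did not pass the test. ABCG2 changed sign with the values as deposited and without sensitive replicate 1 (0.06) or paclitaxel-resistant replicate 3 (0.03), and MCL1 did with the mean of its probe sets or without those ending in _x_at or _s_at.

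The other 16 lists were not called in the paclitaxel-resistant line. Of 17 drug transporters ABCB1 and ABCA2 rose and ABCC10 fell (adjusted p = 0.852), and the calls of ABCA2 and ABCC10 ended with some single arrays left out, at adjusted p of up to 0.0521 and 0.0628. Of 16 tubulins TUBA4A fell by 1.19 ± 0.15 (adjusted p = 0.829 for the list). Mitosis had 7 members higher and 5 lower (adjusted p = 0.665), DNA replication 2 and 5 (0.665), apoptosis regulators 3 and 8 (0.234) and interferon-stimulated genes 7 and 6 (0.665). Epithelial genes had 6 and 3 (0.251), mesenchymal genes 9 and 9 (0.842) and integrins and cell adhesion 7 and 7 (0.852). Glycolysis and hypoxia had 5 and 11 (0.0640), heat shock proteins 6 and 2 (0.172), xenobiotic metabolism 4 and 12 (0.292) and receptor tyrosine kinases 9 and 5 (0.182). Stem-cell genes had 7 and 6 (0.821), oxidative phosphorylation 6 and 1 (0.210) and ribosomal proteins 2 and 0 (0.665). Oxidative phosphorylation was called higher without sensitive replicate 1 (adjusted p = 0.0319). Glycolysis and hypoxia was called lower without paclitaxel-resistant replicate 3 (adjusted p = 0.0175). It was also called lower with the values as deposited (0.0162), with arrays centred on their medians (0.0209), with the mean of the probe sets (0.0339) and with a mean-variance trend and robust spread (0.0391). Adjusted over the list alone, mitosis had 10 higher and 7 lower and xenobiotic metabolism 10 and 13. Among members named after their values were seen, BST2 fell by 3.78 ± 0.20, the Notch target HEY1 by 2.41 ± 0.17 and the pro-apoptotic BAX by 1.18 ± 0.14, and the receptor MET rose by 2.32 ± 0.33 and the adhesion molecule CDH11 by 1.95 ± 0.24. Median and mean differed in sign in the transporter, interferon, mesenchymal, stem-cell and ribosomal lists. Among markers of other cell types 5 of 12 luminal genes rose (FOXA1, TFF1, TFF3, AGR2 and SPDEF; median 0.27), of which TFF1 rose by 2.55 ± 0.20. LCP1 alone rose among 9 blood cell markers, MITF alone among 7 melanocytic ones, and PDGFRB rose and COL6A3 fell among 11 fibroblast ones. In total 2579 genes were called with limma, 1295 higher and 1284 lower, against 3879 at an unadjusted p below 0.05. Of the called genes 781 changed at least 2-fold (476 higher, 305 lower), and in 34.8% of all genes the groups did not overlap, where chance gives 10%.

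The same genes were called in both lines more often than independent lists would share. Of the calls 1721 were shared in the same direction, 881 higher and 840 lower in both, where independent lists would share 139 and 131. Among them were CD74 (-7.33 in the docetaxel- and -7.48 in the paclitaxel-resistant line), MGMT (-6.60 and -6.59), CCL2 (3.66 and 3.85) and ADGRE1 (3.76 and 4.22). The shared genes made up 68.6% of the docetaxel calls and 66.7% of the paclitaxel calls. Both comparisons use the same 3 sensitive arrays, which makes the differences correlate even with unchanged groups. Across genes, which are not independent replicates, r was 0.866, against a mean of 0.462 and a highest of 0.942 in 100 simulated data sets. The covariance, 0.272, lay above the highest simulated one, 0.0700. Only 3 sensitive arrays were measured, too few for 2 in each of a pair of separate control sets, so a share of the overlap that stems from the controls cannot be removed. The shared count was 1049 without the arrays of lowest and highest median. By the moderated F test 2883 genes differed among the 3 groups, against 4183 at an unadjusted p below 0.05.

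**Figure D4:**
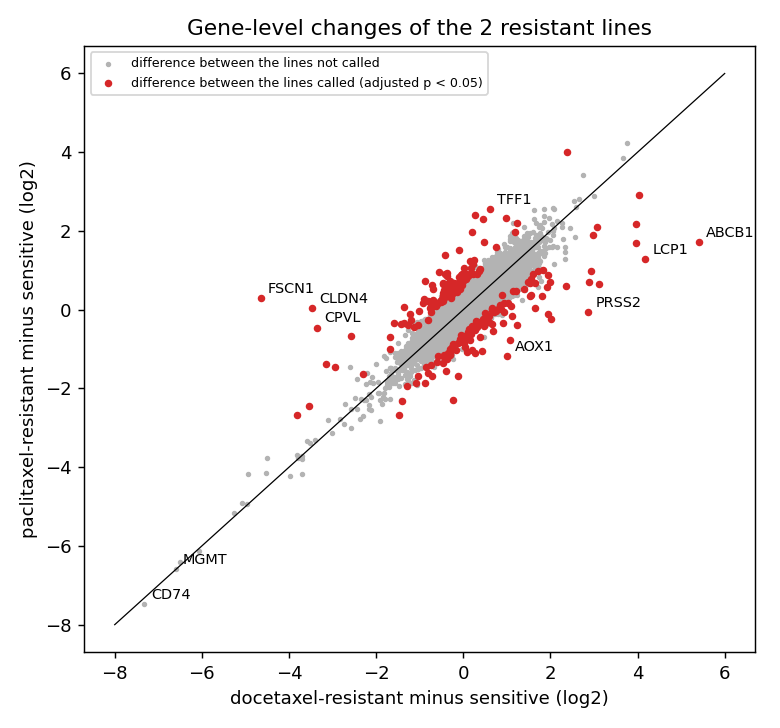
Log2 difference of each gene from sensitive cells in the docetaxel-resistant line (horizontal axis) and in the paclitaxel-resistant line (vertical axis). The line marks equal differences, and genes called between the lines are marked in red. Of the 1721 genes called in both in the same direction, 52 were also called between the lines, ABCB1 among them. FSCN1, CLDN4 and ABCB1 lie off the line.

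The third comparison sets the 2 resistant lines against each other, at doses that differ (2 nM docetaxel and 7 nM paclitaxel), so that drug, dose and line change together. FSCN1 was higher in the paclitaxel-resistant line by 4.95 ± 0.16 (SE, n = 3 per group, adjusted p = 3.84e-08). Its mean deposited intensity was 943 ± 114 (SD) there and 751 ± 126 in sensitive cells. CLDN4, a tight junction protein, was higher by 3.49 ± 0.17 (adjusted p = 6.80e-07) and the carboxypeptidase CPVL by 2.91 ± 0.14 (adjusted p = 6.80e-07), with a level near 0 in the docetaxel-resistant line that makes the size depend on the pseudocount. ABCB1 was lower in the paclitaxel-resistant line (-3.69 ± 0.19, adjusted p = 1.62e-06), as was LCP1 (-2.89 ± 0.21, adjusted p = 3.80e-05). Higher in the paclitaxel-resistant line were also the secreted trefoil peptides TFF1 (1.95 ± 0.20) and TFF2 (1.76 ± 0.17) and the cancer-testis antigens SSX1 (2.14 ± 0.19) and SSX3 (1.85 ± 0.19). The other probe sets of SSX3 stood at -0.01 and -0.12, and their mean with the one used was 0.57. The same held for ADAM8 (1.89 ± 0.18), the myosin light chain kinase MYLK (1.81 ± 0.23) and S100A4 (1.77 ± 0.15). Lower there were also trypsinogen PRSS2 (-2.93 ± 0.26), TMEM243 (-2.45 ± 0.24), USP33 (-2.27 ± 0.31) and TRBC1 (-2.23 ± 0.18). The same held for the oxidase AOX1 (-2.19 ± 0.25), ABCB4 (-2.06 ± 0.23), MXRA8 (-2.06 ± 0.20) and the heat shock protein DNAJB4 (-2.18 ± 0.44, adjusted p = 0.0290). The call of DNAJB4 ended without sensitive replicate 3 (adjusted p = 0.0513), docetaxel-resistant replicate 2 (0.0748), paclitaxel-resistant replicate 2 (0.132) or paclitaxel-resistant replicate 3 (0.119). It also ended with the values as deposited (0.0608), a pseudocount of 1 (0.0933) or a replicate block (0.0617). The call of USP33 ended with a pseudocount of 1 (adjusted p = 0.0722), and without probe sets ending in _x_at or _s_at its value was -0.91. With a pseudocount of 1 CLDN4 stood at 5.30, CPVL at 6.31 and ABCB4 at -3.12. The other, lower probe set of PRSS2 stood at -1.30 between the lines. Against sensitive cells it stood at 0.86 in the paclitaxel-resistant line, where the PRSS2 probe set used stood at -0.06. The other, lower probe set of SSX1 stood at 0.73 between the lines.

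Of the 235 genes called between the lines, 66 were called against sensitive cells in the docetaxel comparison only, 90 in the paclitaxel comparison only, 52 in both in the same direction, 8 in both in opposite directions and 19 in neither. GUSB, a lysosomal glucuronidase, fell by 0.87 ± 0.15 in the docetaxel-resistant line and rose by 0.73 ± 0.15 in the paclitaxel-resistant line. AOX1 rose by 1.01 ± 0.25 and fell by 1.18 ± 0.25, and its docetaxel call ended without docetaxel-resistant replicate 3 (0.87, adjusted p = 0.0634), without the arrays of lowest and highest median (0.59) and with the covariate (0.61). TENT5C, MAP3K7CL and RPH3AL were the other opposite genes with the largest differences (-1.64 ± 0.13, -1.83 ± 0.21 and 1.23 ± 0.17 between the lines). Their calls against sensitive cells held less well. The paclitaxel call of TENT5C (-0.40, adjusted p = 0.0411) ended in 13 of 20 settings, at an adjusted p of up to 0.145. The docetaxel call of RPH3AL (-0.70, adjusted p = 0.0137) ended in 5 of 19 settings, with 0.0507 without sensitive replicate 3 and 0.0600 without docetaxel-resistant replicate 3. Its paclitaxel call (0.53, adjusted p = 0.0494) ended in 14 of 19, at up to 0.163. The paclitaxel call of MAP3K7CL (-0.77, adjusted p = 0.0238) ended without sensitive replicate 3 (-0.52, adjusted p = 0.0751), without paclitaxel-resistant replicate 1 (0.0636) or 3 (0.0899) and with the values as deposited (0.0551).

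None of the 22 lists was called between the lines by limma's camera, against 3 at an unadjusted p below 0.05 (receptor tyrosine kinases and growth factors, glycolysis and hypoxia, and tubulins) and 0 unadjusted with an estimated correlation. The receptor tyrosine kinase list came nearest, with 4 of 41 members higher in the paclitaxel-resistant line, none lower and 37 not called, and 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.0638). The 4 were the ERK phosphatases DUSP4 (1.06 ± 0.13) and DUSP6 (1.16 ± 0.18), the growth factor NRG1 (0.94 ± 0.18) and the receptor signalling inhibitor SPRY4 (0.82 ± 0.15), named after their values were seen. NRG1 lost its call with any 1 of the 6 resistant arrays left out (adjusted p up to 0.105), SPRY4 with any 1 of 5 of them (up to 0.0838, all but paclitaxel-resistant replicate 2), and DUSP6 with the values as deposited. The list itself was called without docetaxel-resistant replicate 1 (adjusted p = 0.0174) and with a mean-variance trend and robust spread (adjusted p = 0.0476). Without docetaxel-resistant replicate 1 DNA replication was also called lower (adjusted p = 0.0379), and without docetaxel-resistant replicate 3 mitosis was called higher (adjusted p = 0.00593) and antigen presentation lower (adjusted p = 0.0486). The latter 2 were also called without the arrays of lowest and highest median (0.00469 and 0.0334). Median and mean differed in sign in the apoptosis, matrix protease and heat shock lists.

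The lines did not differ detectably in the other genes named in advance. The difference, paclitaxel- minus docetaxel-resistant, had a 95% interval of 0.09 to 0.64 in TUBB3 (adjusted p = 0.202), -0.29 to 0.31 in TUBB2A and -0.28 to 0.28 in TUBB6. It was -0.29 to 0.28 in STMN1, -0.04 to 0.56 in MAPT, -0.35 to 0.30 in ABCC1 and -0.25 to 0.46 in ABCG2. For the regulators of apoptosis and the cell cycle it was -0.26 to 0.36 in BCL2, -0.30 to 0.27 in BCL2L1, -0.52 to 0.34 in MCL1 and 0.08 to 0.86 in CDKN1A (adjusted p = 0.252). In 11269 genes (94.2%) the 95% interval of the difference lay within 1 log2 unit of 0. The 235 called genes were 117 higher and 118 lower in the paclitaxel-resistant line, against 1564 at an unadjusted p below 0.05, and 78 differed at least 2-fold (41 higher, 37 lower). In 20.4% of genes the groups did not overlap, where chance gives 10%. The count was 96, 78 and 109 without docetaxel-resistant replicates 1, 2 and 3, and 146, 104 and 96 without paclitaxel-resistant replicates 1, 2 and 3.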

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

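In the docetaxel-resistant line ABCB1 and its neighbours on chromosome 7 were raised together; all tests of it were chosen after this was seen, and only for the one with the within-group axis was the deciding outcome set down before its result. The median log2 difference of the 6 genes was 2.44; none (0) of 1000 shuffled gene orders gave a 6-gene window as high, the highest being 1.73, which argues against a chance order of changed genes, although shuffling treats genes as exchangeable. Probes that also bind related transporters would leave the 4 neighbours that are not transporters near 0, but DMTF1, TMEM243, TP53TG1 and CROT had a median of 2.42; for ABCB4 alone the paclitaxel-resistant value, -0.11, does not decide, since ABCB1 itself was far lower there. With the within-group axis as a covariate the median of the 6 was 2.41. A candidate explanation is more copies of this stretch of the chromosome in the docetaxel-resistant line; no DNA was measured, and shared regulation of neighbours stays open too.

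Whole chromosomes were shifted in single lines; all tests of this were chosen after it was seen, and only for those with the within-group axis was the deciding outcome set down before the result. Genes of chromosome 15 at or above the median level had a median of 0.46 in the docetaxel- and 0.01 in the paclitaxel-resistant line (between the lines -0.34), and genes of chromosome 22 medians of -0.05 and 0.37 (between the lines 0.36). In none (0) of 1000 shuffles did any chromosome lie as far from the median of all genes (highest 0.148), which argues against chance placement for either, and with the axis as a covariate the medians were -0.32 and 0.34. A bias with base composition would shift chromosome 19, rich in genes and in guanine and cytosine like chromosome 22. Its median between the lines was 0.036, which bears on the difference between the lines only. Against sensitive cells chromosome 19 stood at -0.24 in the docetaxel- and -0.16 in the paclitaxel-resistant line. With the covariate these medians were -0.049 and -0.030, and a bias in those comparisons was not tested. A candidate explanation is a change in copy number of chromosomes 15 and 22 or of parts of them in 1 line each. No DNA was measured, and no other biological explanation was tested.

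Of the class II genes in the antigen presentation list 5 were lowered, with CD74, in both resistant lines, and both tests of this were chosen after it was seen. HLA-DRA, HLA-DRB1, HLA-DPA1, HLA-DPB1, HLA-DMA and CD74 were called lower in both lines, HLA-DMB in the docetaxel-resistant line only, and the class I genes HLA-B, HLA-E, HLA-F and HLA-G in both, while a further probe set of HLA-DPA1 stood at -0.22 and -0.08. Blood cells in the sensitive cultures would have brought their other abundant transcripts, but the lower median of the blood cell markers was -0.044. The mean intensity in sensitive, docetaxel- and paclitaxel-resistant cells was 1269, 1332 and 741 in SRGN, 106, 116 and 109 in CD53 and 378, 412 and 447 in HBB. LCP1 rose, and the other markers lay near background and could show no fall. In sensitive cells their mean intensity was 9.29 in PTPRC, 3.09 in LYZ, 13.8 in CORO1A, 24.1 in CD14 and 35.7 in CD3D, beside 11082 in CD74. Probes shared among class II genes would not reach CD74, which stood at -7.33 in the docetaxel-resistant line, but CD74 is part of the pattern, so whether the class II chains fell one by one or partly through shared probes cannot be told apart. CIITA, the regulator of these genes, stood at 0.28 and 0.21 and was not called, so the step at which expression fell stays open; as the same sensitive cells serve both comparisons, a feature of the sensitive cultures may contribute to the change in both lines, and this was not tested.

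Other splits of the arrays were counted by tests set before their results were seen. The 6 arrays of 2 groups form 10 splits, too few for a share under 0.05: the real split (1 of 10 with as many calls in each case) called 2510 genes in the docetaxel comparison, 2579 in the paclitaxel comparison and 235 between the lines, and the highest of the other splits called 0. For gene lists the real split called 5 in the docetaxel comparison (highest other 6), and 3 of 10 splits, the real one included, called at least as many. A share of 0.05 or more was the outcome set beforehand for chance, but 10 splits allow no smaller one, so meeting it decides nothing. Another split called 6 lists, so the number of called lists alone did not set the real split apart. In the paclitaxel comparison the real split called 6 (highest other 4, 1 of 10), again with too few splits to decide. Between the lines the real split called 0 lists, while another split called 5. Of 100 drawn splits of the 9 arrays, the real one included, 1 gave as many genes by the F test (2883, highest other 1981). Likewise 1 of 100 gave as many shared calls (1721, highest other 1464). These shares lie under the 0.05 set beforehand, which argues against chance for both counts without excluding it. The part of the overlap that stems from the shared controls cannot be removed by such splits.

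The genes named between the resistant lines were the 10 largest called increases and the 10 largest called decreases that met the rule for named genes, and MAP3K7CL, TENT5C, RPH3AL and GUSB (with AOX1) for calls in opposite directions. As paclitaxel- minus docetaxel-resistant on the log2 scale they were ABCB1 (-3.69), PRSS2 (-2.93), LCP1 (-2.89), TMEM243 (-2.45), USP33 (-2.27), TRBC1 (-2.23), AOX1 (-2.19), DNAJB4 (-2.18), ABCB4 (-2.06), MXRA8 (-2.06), MAP3K7CL (-1.83), TENT5C (-1.64), RPH3AL (1.23), GUSB (1.61), TFF2 (1.76), S100A4 (1.77), MYLK (1.81), SSX3 (1.85), ADAM8 (1.89), TFF1 (1.95), SSX1 (2.14), CPVL (2.91), CLDN4 (3.49) and FSCN1 (4.95). ABCB1, TMEM243 and ABCB4 belong to the run on chromosome 7. Others also lay beside shifted neighbours. TENT5C lies in a window from VTCN1 to WARS2 on chromosome 1, which also holds WDR3 (window median between the lines -1.14). USP33 and DNAJB4 lie in a window from PIGK to DNAJB4 on chromosome 1 (-0.77). TFF1 and TFF2 lie in a window from RIPK4 to TFF1 on chromosome 21 (0.97). Chance placement was not tested for these further windows. The level of CPVL in the docetaxel-resistant line was 0.503, so its difference rests on the pseudocount and is no measured ratio. The second, lower probe set of FSCN1 stood at -2.83 in the docetaxel- and 0.42 in the paclitaxel-resistant line.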

How the results depend on the processing

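The counts depended on the settings to different degrees, and except where the construction shows it the cause was not tested. The docetaxel comparison called 2510 genes, 1431 without _x_at and _s_at probe sets (a smaller set of genes), 1368 at an adjusted p below 0.01, 774 with a 2-fold minimum, 1338 without the arrays of lowest and highest median, and 1643 (without docetaxel-resistant replicate 3) to 2582 with 1 array left out. The paclitaxel comparison called 2579, 1495 without _x_at and _s_at probe sets, 1458 below 0.01 and 781 with a 2-fold minimum. Between the lines 235 were called, 143 with the values as deposited, 72 with a pseudocount of 1, 110 without _x_at and _s_at probe sets, 785 with array weights, 139 with a replicate block, 136 without the arrays of lowest and highest median, 544 with the within-group axis as a covariate, 72 below 0.01, 78 with a 2-fold minimum, and 78 (without docetaxel-resistant replicate 2) to 280 with 1 array left out. The F test called 2883 genes and 1627 without _x_at and _s_at probe sets, and the shared calls were 1721, 991 without those probe sets and 1049 without the arrays of lowest and highest median. The lists called were 5 in the docetaxel comparison, 3 without _x_at and _s_at probe sets, 8 without the arrays of lowest and highest median, 9 with the covariate, 0 with an estimated correlation and 5 to 8 with 1 array left out (8 without sensitive replicate 2 and without docetaxel-resistant replicate 3). In the paclitaxel comparison they were 6, 2 without _x_at and _s_at probe sets and 0 with an estimated correlation. Between the lines they were 0, 1 with a mean-variance trend and robust spread, 2 without the arrays of lowest and highest median and 0 to 2 with 1 array left out. With a replicate block 2291, 2387 and 139 genes were called in the 3 comparisons. Of the called genes 51.3%, 50.2% and 49.8% were higher, and 64.4%, 53.0% and 37.1% with the values as deposited. No scaling moved the median of all genes by more than 0.1.

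Values that changed sign all belonged to comparisons in which the gene was not called at the settings of the report; BCL2L1 was called against sensitive cells, but not between the lines, and MCL1 was called in the docetaxel comparison with genes at or above the median level only (adjusted p = 0.0462). MCL1 went from 0.56 to -0.21 in the docetaxel comparison without _x_at and _s_at probe sets, in the paclitaxel comparison to -0.16 with the mean of its probe sets and -0.025 without _x_at and _s_at probe sets, and between the lines to 0.19 without those probe sets, 0.00777 with array weights, 0.031 without the arrays of lowest and highest median and -0.21 to 0.043 with 1 array left out. ABCG2 in the paclitaxel comparison went to 0.027 with the values as deposited and -0.18 to 0.056 with 1 array left out. Between the lines ABCC1 went to 0.10 with the mean of its probe sets, 0.00870 with array weights and -0.13 to 0.079 with 1 array left out; TUBB2A to -0.035 with the values as deposited, -0.035 with array weights, -0.00515 without the arrays of lowest and highest median, -0.00586 with the covariate and -0.066 to 0.11 with 1 array left out; TUBB6 to -0.061 to 0.072 with 1 array left out. STMN1 went to 0.00842 with array weights, 0.033 without the arrays of lowest and highest median, 0.025 with the covariate and -0.049 to 0.033 with 1 array left out, BCL2 to -0.00928 with the mean of its probe sets, -0.050 without the arrays of lowest and highest median and -0.049 to 0.14 with 1 array left out, and BCL2L1 to -0.10 to 0.052 with 1 array left out.

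Of 143 values of named genes 122 kept their direction and call under every setting in which they were measured, and of the 114 called ones 103. The lists of antigen presentation and of cholesterol and lipid synthesis were called in both lines in all 20 settings that kept the preset inter-gene correlation, and in neither line with an estimated one (adjusted p = 0.290 and 0.352). The first axis of the within-group deviations held 43.4% of their variance, with sensitive replicate 2 and docetaxel-resistant replicate 3 at its ends; fits without the arrays of lowest and highest median and with this axis as a covariate were chosen after the data were seen. With the covariate 1743, 2423 and 544 genes were called and 1307 were shared; of the genes shared before, 580 of 881 higher and 558 of 840 lower ones stayed called in both. The data did not show that the replicate numbers pair the arrays. After removal of group means, arrays of the same number correlated across genes at -0.45 to 0.34 (3 of 9 over 0.1). Arrays of different number correlated at -0.45 to 0.47 (7 of 18), and genes are not independent replicates. With 3 arrays per group the deviations depend on each other, so pairing is not excluded. The precision is set by 3 arrays per group and by the share of probe sets near background, where a pseudocount of 1 spreads low values and the offset of 16 shrinks them.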

Other observations

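Further chromosomes were shifted in both lines against sensitive cells, in the genes at or above the median level. On chromosome 18 the median was 0.69 in the docetaxel- and 0.67 in the paclitaxel-resistant line. Of its 67 genes 38 were higher and 0 lower in the former, and 37 higher and 2 lower in the latter. Per array, against the sensitive mean, its median was 0.58, 0.64 and 1.05 in docetaxel-resistant and 0.77, 0.66 and 0.61 in paclitaxel-resistant replicates 1 to 3. With the within-group axis as a covariate the medians of chromosome 18 were 0.53 and 0.60. On chromosome 10 the median was -0.26 and -0.43, with 71 and 96 of 221 genes lower. Per array the median of chromosome 15 against the sensitive mean was 0.42, 0.43 and 0.51 in the docetaxel-resistant and 0.07, -0.01 and -0.03 in the paclitaxel-resistant arrays, and that of chromosome 22 was 0.02, 0.05 and -0.04 and 0.43, 0.38 and 0.33. Among other runs of raised neighbours were 6 genes from LPAR3 to ZNHIT6 on chromosome 1 (window median 1.501 in the docetaxel- and 1.096 in the paclitaxel-resistant line), runs from TBL1X to MID1 and from TXLNG to SCML2 on chromosome X (1.34 and 1.31 in the docetaxel-resistant line) and one from GTF2B to LRRC8D on chromosome 1 (1.31 there). Others were the 6 genes from TFF3 to SLC37A1 on chromosome 21, of which 3 are trefoil genes (window median 1.62 in the paclitaxel-resistant line), and the 6 from APOL6 to APOL1 on chromosome 22, which include RBFOX2 (1.25 there). The readings of 18S ribosomal control probes were 83.8, 100 and 126 in sensitive, 130, 167 and 178 in docetaxel-resistant and 269, 28.0 and 20.8 in paclitaxel-resistant replicates 1 to 3. Those of 28S were 143, 148 and 174, then 254, 243 and 276, then 163, 184 and 72.0 in the same order. Both were thus higher in all docetaxel-resistant than in all sensitive arrays.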
